A study of Mus musculus with 4 samples.

How the data were processed

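RNA was measured by sequencing in 4 libraries of mouse bone marrow cells cultured with RANKL, the cytokine that drives macrophage precursors to become osteoclasts, for 3 days. The labels assign 2 libraries to a Nat10 conditional knockout genotype and 2 to wild type (WT). Per the labels, cells were washed in buffer with cycloheximide, an inhibitor of translation elongation, before lysis, ribosomal RNA was removed with a depletion kit, and libraries were made with an Illumina mRNA kit. The labels give no batch, no sex of the mice and no statement that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

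The authors deposited one table of raw counts per gene, whole numbers with no normalization, with Ensembl gene identifiers, symbols and coordinates in each row, per the file headers. Every gene listed there is protein-coding, so long non-coding RNAs such as Xist and Malat1 were not analysed here. Per the submitters' processing notes, the tools were fastp 0.20.0, STAR 2.7.9a and featureCounts 2.0, and the genome build was mm39 (GRCm39). The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes, and reads shared between near-identical copies such as ribosomal protein genes and their pseudogenes, could be counted under either gene. Coordinates are printed as the deposited table gives them.

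Total counts were 11291993 and 14097638 in the libraries labelled Nat10 cKO and 10037338 and 13063821 in the WT libraries. The table holds 21834 genes, of which 6402 had no count in any library. Genes were kept with the default rule of filterByExpr, which left 11448. Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with the group as the only term and Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p under 0.05 are called higher or lower. Fold changes are log2 values, libraries labelled Nat10 cKO minus WT, with the standard error (SE) of the fit. Levels are given as CPM, counts scaled to a common library size with TMM factors, as mean ± SD of 2 libraries. A bound on a fold against a group with no count used a floor of 3 counts over that group, which covers counting error only. That bound was scaled by total counts without TMM factors.

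The 27 gene lists, the rule for the genes named, the design and most alternatives were fixed before the data were examined. Lists with at least 5 measured members, 24 of the 27, were tested with camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation has few residual degrees of freedom at 2 libraries per group. Genes named are Nat10, Nfatc1 and 12 osteoclast and macrophage genes, the 10 higher and the 10 lower called genes with the largest absolute log2 fold change among those with a mean of at least 10 CPM and no overlap between the groups, leaving out predicted genes, and up to 4 members per list with the smallest p. Of the genes this rule takes, 1 is not reported here. Any other gene named was chosen after its values were seen. These are the list members that went against their list or did not pass in it, Sp7, and the genes of the pathways, the second stromal list and the liver markers in the closing section. Pathway sets came from the pathway annotation in the deposited table, for sets of 10 to 300 tested genes.

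Replicates were compared before they were averaged. A chi-square of the counts of the WT replicates gave 6.16 per gene over 11776 genes with at least 10 counts, and that of the replicates labelled Nat10 cKO gave 11.2 over 12175 genes, so both pairs differed by more than sampling noise. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.990 within each group and 0.961 to 0.965 between groups. Y-linked genes had 0 to 2 counts per library. The biological coefficient of variation was 8.28%.

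The whole procedure was tested on simulated data first. Counts for the 11448 genes of this comparison were drawn from their means, library sizes and the dispersion trend, with 200 genes changed, and 11291 passed the filter. No gene had a dispersion of its own, so the count of false calls may be too low. The adjustment is stricter with 200 changed genes than with more, so the recovery below need not hold for the data. Among the changed genes that did, the test recovered 55.38% of those changed by 1.5-fold, 77.27% by 2-fold and 96.97% by 4-fold, and called 2 of 11094 unchanged genes. Camera with the preset correlation called 0 of 20 lists of unchanged genes. Each gene was drawn independently, so this does not test lists whose members vary together, such as ribosomal proteins (estimated correlation 0.73).

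Alternatives were RLE factors, upper-quartile factors, library size only, no filter on low counts, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. When a library is left out, 1 group has a single library, which is assumed to vary like the others. The spread between replicates then comes from the other group's pair alone. A lost or gained call can therefore reflect that spread rather than the left-out library. A correction for transcript length and GC content by natural splines with 4 degrees of freedom each, over the 99.8% of tested genes with both values in a GENCODE annotation of an earlier mouse build, and a fit without the 10 genes with the largest counts were added after seeing the data.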

Results

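Gene expression was measured in cultures of mouse bone marrow derived monocytes and macrophages after 3 days of RANKL induction, which turns these precursors into bone-resorbing osteoclasts. The 4 libraries form 2 groups of 2, one labelled as a conditional knockout (cKO) of Nat10 and one labelled wild type (WT). Nat10 encodes the enzyme that writes N4-acetylcytidine, a cytidine modification of RNA, and the comparison asks how its loss changes the transcripts of cells on the way to osteoclasts. Total counts ranged from 10037338 to 14097638 per library, and 13742 to 14032 genes had at least 1 count. Fold changes are log2 values, libraries labelled Nat10 cKO minus WT, and each level is a mean ± SD in CPM, counts scaled to a common library size, with n = 2 libraries per group.

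The targeted gene was measured first. Nat10 (ENSMUSG00000027185, chromosome 2, 103551601 to 103591615 on GRCm39) had 184 and 205 counts in the libraries labelled Nat10 cKO and 165 and 238 in the WT libraries. Its level was 15.1 ± 1.12 CPM (SD, n = 2) against 17.7 ± 1.27 CPM, a log2 fold change of -0.24 (SE 0.153, 95% interval -0.56 to 0.08, edgeR adjusted p = 0.263). Both libraries labelled Nat10 cKO lay below both WT libraries, but the difference did not pass the test, and the interval excludes a loss of 1 on the log2 scale. Which exons the deletion covers is not given in the sources used here, and a count over the whole gene does not check a deletion of some exons. The groups are named by their labels throughout, and each direction below rests on those labels.

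Nfatc1, the transcription factor that drives osteoclast differentiation and the transcript named in the title of the series, was higher in the libraries labelled Nat10 cKO. Nfatc1 (ENSMUSG00000033016, chromosome 18, 80649420 to 80756286 on GRCm39) stood at 155 ± 3.83 CPM (SD, n = 2) against 106 ± 9.12 CPM. Its log2 fold change was 0.55 (SE 0.102, edgeR adjusted p = 0.000502), and both libraries labelled Nat10 cKO lay above both WT libraries. Without WT replicate 2 the log2 fold change was 0.45 and the adjusted p 0.0587, the highest of a range that began at 2.01e-06 with other libraries left out. The libraries measure RNA, and translation of Nfatc1 was not analysed here.

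**Figure D1:**
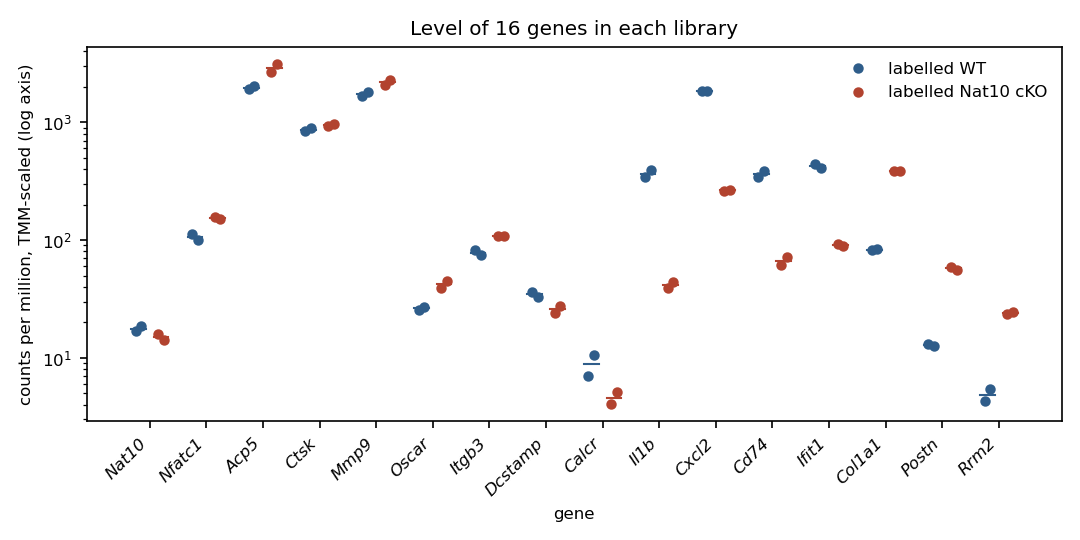
Level of 16 genes in each library, in TMM-scaled CPM on a log axis, with WT libraries in blue, libraries labelled Nat10 cKO in red and a bar at each group's mean of 2 libraries. Nat10 stood at 15.1 CPM in the libraries labelled Nat10 cKO and 17.7 CPM in WT, while Il1b stood at 41.9 and 367 CPM and Col1a1 at 384 and 82.8 CPM.

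Across the transcriptome, 3302 of 11448 tested genes differed between the groups in the edgeR test, 1652 higher and 1650 lower in the libraries labelled Nat10 cKO. Of these, 662 were higher and 267 lower by at least 1 on the log2 scale. The named genes with the largest rises were Thbs2, a matrix-associated thrombospondin (2.94, SE 0.164), the matricellular genes Ccn1 (2.45) and Ccn2 (2.18), the chemokine Cxcl12 (2.42), the growth factor receptor adaptor Grb10 (2.31), the ribonucleotide reductase subunit Rrm2 (2.30), the collagen Col1a1 (2.21), the myosin light chain Myl9 (2.21), Postn (2.17) and the mesenchymal transcription factor Prrx1 (2.14). Those with the largest falls were Alb, the serum albumin of liver (-5.56, SE 0.419), the cytokines Il6 (-3.57) and Il1b (-3.13), the chemokines Cxcl1 (-3.23) and Cxcl2 (-2.80), the class I histocompatibility gene H2-M2 (-3.27), the interferon-inducible GTPase Gbp5 (-3.22), the endothelial growth factor receptor Kdr (-3.12), Gpr141 (-3.05) and Lad1 (-2.84). Groups did not overlap for 7281 of the tested genes (63.6%), where chance gives 33.3%. The split of calls depended on scaling, with 2247 higher and 1110 lower under upper-quartile factors and 2026 higher and 1252 lower with library size only. DESeq2 called 2114 genes, and without WT replicate 1 or WT replicate 2 the edgeR test called 2068 or 1837.

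**Figure D2:**
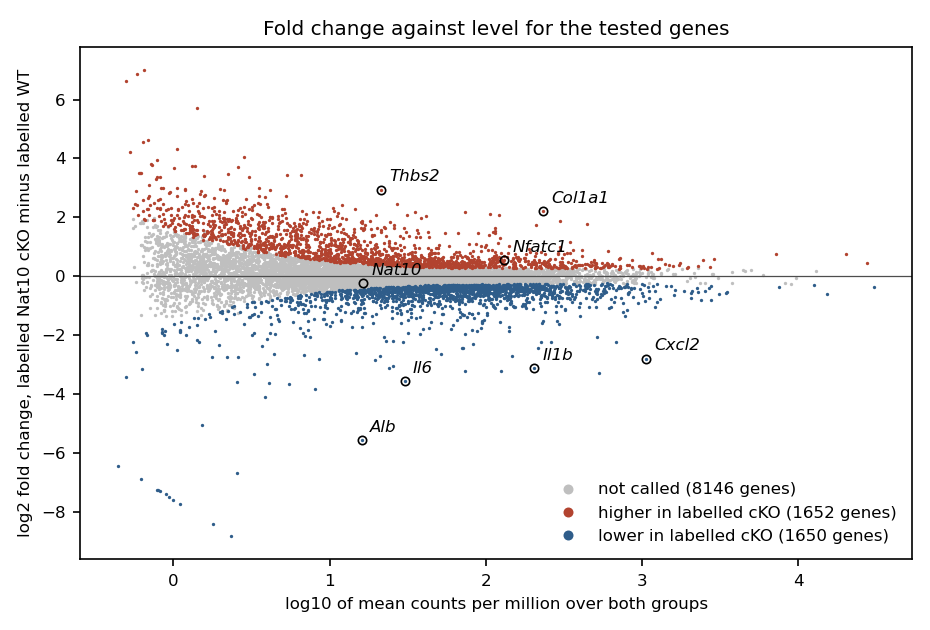
Log2 fold change of each tested gene (libraries labelled Nat10 cKO minus WT) against the log10 of its mean CPM, with the 1652 genes called higher in red, the 1650 called lower in blue and the others in grey. Fitted values beyond about 6 in size belong to genes with few or no counts in one group, and named genes such as Il6 (-3.57) and Thbs2 (2.94) are circled.

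Genes of the osteoclast itself moved in both directions. In the list for resorption machinery, 6 of 20 measured members rose and 6 fell, over all genes and adjusted over the list alone. Acp5, the tartrate-resistant acid phosphatase used to stain osteoclasts, rose by 0.56 (SE 0.0988, 2913 ± 305 against 1973 ± 71.2 CPM). The sodium/proton exchanger Slc9b2 rose by 1.08, the proton pump subunit Atp6v0d2 by 0.75 and the collagen receptor Oscar by 0.68. Calcr, the calcitonin receptor, fell by 0.95, the membrane metalloproteinase Mmp14 fell by 0.81 and the chloride transporter Clcn7 fell by 0.72. Ctsk, the main collagen-degrading protease of osteoclasts, had a log2 fold change of 0.14 (SE 0.0909, adjusted p = 0.283), and Mmp9 rose by 0.32. The list as a whole did not pass (median 0.03, mean -0.000886, camera adjusted p = 0.875), and its median was negative after the length and GC correction (-0.015) and without cKO replicate 1 (-0.012), cKO replicate 2 (-0.00028) or WT replicate 1 (-0.012). With WT replicate 2 left out, 4 members rose and 3 fell. Leaving out WT replicate 2 ended the calls of Calcr (-0.61), Mmp9 (0.36) and the integrin Itgb3 (0.40, against 0.47 in the full set), and leaving out WT replicate 1 that of Mmp9 (0.26). DESeq2 also ended the call of Calcr (-0.96).

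In the cell fusion list, 6 of 11 measured members rose and 3 fell over all genes, and 7 rose and 4 fell adjusted over the list alone. The metalloprotease Adam8 (0.93), Atp6v0d2 (0.75) and the myosin Myo1d (0.80) rose, and the hyaluronan receptor Cd44 fell by 0.65. The fusion protein genes Ocstamp and Dcstamp went apart, with Ocstamp at 0.49 (adjusted p = 0.00807) and Dcstamp at -0.42 (adjusted p = 0.0186). The list did not pass (median 0.47, camera adjusted p = 0.0852), and without WT replicate 1 or WT replicate 2 its falling members numbered 1, as with upper-quartile factors, while its median was 0.31 without cKO replicate 2. The call of Ocstamp ended without cKO replicate 2 (0.29) and without WT replicate 1 (0.38). That of Dcstamp ended with upper-quartile factors (-0.32), in DESeq2 (-0.44), and without cKO replicate 1 (-0.34), WT replicate 1 (-0.36) or WT replicate 2 (-0.50).

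Among genes of RANK signalling and osteoclast transcription factors, 8 of 29 rose and 5 fell over all genes, and 10 rose and 5 fell adjusted over the list alone (median 0.06, camera adjusted p = 0.638). The immunoreceptor Trem2 rose by 0.79 and its adaptor Tyrobp by 0.76, while the NF-kappa B subunit Nfkb2 fell by 1.02 and the kinase Ikbkb fell by 0.72. Tnfrsf11a, the receptor for RANKL, had a log2 fold change of 0.18 (adjusted p = 0.258), and Csf1r, the receptor for M-CSF, one of 0.25 (adjusted p = 0.0406), a call that ended without WT replicate 1 (0.24) or WT replicate 2 (0.26). Without WT replicate 1, 5 members of the list rose and 3 fell, and without WT replicate 2, 3 rose and 3 fell, while the median was 0.017 without cKO replicate 1 and 0.10 without cKO replicate 2. Of 17 negative regulators of osteoclast formation, 2 rose and 6 fell over all genes, and 3 rose and 6 fell adjusted over the list alone (median -0.13, camera adjusted p = 0.0566). That list passed without cKO replicate 1 (camera adjusted p = 0.0338) or cKO replicate 2 (camera adjusted p = 0.0199), in a range up to 0.463 over its alternatives. The NF-kappa B inhibitors Tnfaip3 (-1.23) and Nfkbia (-1.04) and the cytokine signalling suppressors Socs1 (-1.05) and Socs3 (-0.63) fell. Members of the list went both ways, with log2 fold changes from -1.23 to 1.19. In that list, 1 member rose and 5 fell without WT replicate 2. Irf8 was at -0.23 (adjusted p = 0.116).

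Proton pump and lysosome genes showed no common direction. Of 18 V-ATPase subunits, 2 rose and 5 fell over all genes and adjusted over the list alone, Atp6v0d2 among the former and Atp6v1e1 (-0.41), Atp6v0b (-0.41) and Atp6v1h (-0.38) among the latter (median -0.03, camera adjusted p = 0.699). Without WT replicate 2, 1 subunit rose and 0 fell, and without WT replicate 1, 1 rose and 1 fell. The median of these subunits was positive with upper-quartile factors (0.07), library size only (0.03) and without cKO replicate 1 (0.014). It was -0.093 without cKO replicate 2 and -0.087 without WT replicate 1. Of 24 lysosome and autophagy genes, 1 rose and 2 fell over all genes, and 0 rose and 2 fell adjusted over the list alone (median 0.03, mean -0.03, camera adjusted p = 0.716). The autophagy receptor Sqstm1 fell by 0.82, from 3038 ± 151 to 1720 ± 79.0 CPM. Without either WT library, 0 of these genes rose and 1 fell, and the median was negative without WT replicate 1 (-0.020) and after the length and GC correction (-0.013).

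Inflammatory genes were lower in the libraries labelled Nat10 cKO. Of 21 measured cytokine and chemokine genes, 17 fell and 0 rose over all genes, and 19 fell and 1 rose adjusted over the list alone (median -1.07, camera adjusted p = 3.01e-56). The list's adjusted p was 0.0756 with an estimated correlation. Il1b fell from 367 ± 37.2 to 41.9 ± 3.51 CPM, a log2 fold change of -3.13 (SE 0.114), and Cxcl2 from 1842 ± 19.8 to 264 ± 1.71 CPM. Il1a fell by 2.71, while Il18 (-0.49), Ccl2 (-0.28), Tlr2 (-0.05) and Nos2 (0.22) did not pass over all genes. With upper-quartile factors or library size only, 17 fell and 1 rose. Alb was lower in the same libraries (-5.56).

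Interferon-stimulated genes, which respond to type I interferon, were lower as well. Of 25 measured, 23 fell and 0 rose over all genes and adjusted over the list alone (median -1.29, camera adjusted p = 1.31e-47), with an adjusted p = 0.0756 with an estimated correlation. Ifit1 fell by 2.24, Ifit2 fell by 2.44, Rsad2 fell by 2.07 and Gbp2 fell by 1.87, and Rtp4 (-0.18) and Oas2 (0.05) did not pass. Of 10 measured dendritic cell and MHC class II genes, 6 fell and 0 rose over all genes, and 7 fell and 0 rose adjusted over the list alone (median -1.49, camera adjusted p = 3.33e-16, and adjusted p = 0.0756 with an estimated correlation). The members that fell include the invariant chain Cd74 (-2.44) and the class II genes H2-Aa (-2.64), H2-Ab1 (-1.74) and H2-Eb1 (-2.24), which present antigen, whereas the dendritic cell genes Zbtb46 (-0.24) and Itgax (0.16) did not pass. Markers of macrophages, the undifferentiated cell of the culture, went both ways beside these groups. Of 21 measured, 6 rose and 6 fell over all genes, and 6 rose and 7 fell adjusted over the list alone (median -0.03, mean 0.06, camera adjusted p = 0.536). The chemokine receptor Cx3cr1 rose by 2.04 and the scavenger receptor Cd36 by 0.90, and Adgre1, the antigen of the macrophage marker antibody F4/80, rose by 0.60. The median of the macrophage markers was positive with upper-quartile factors (0.07), library size only (0.04), the length and GC correction (0.03) and without cKO replicate 1 (0.024). It was -0.11 without cKO replicate 2.

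**Figure D3:**
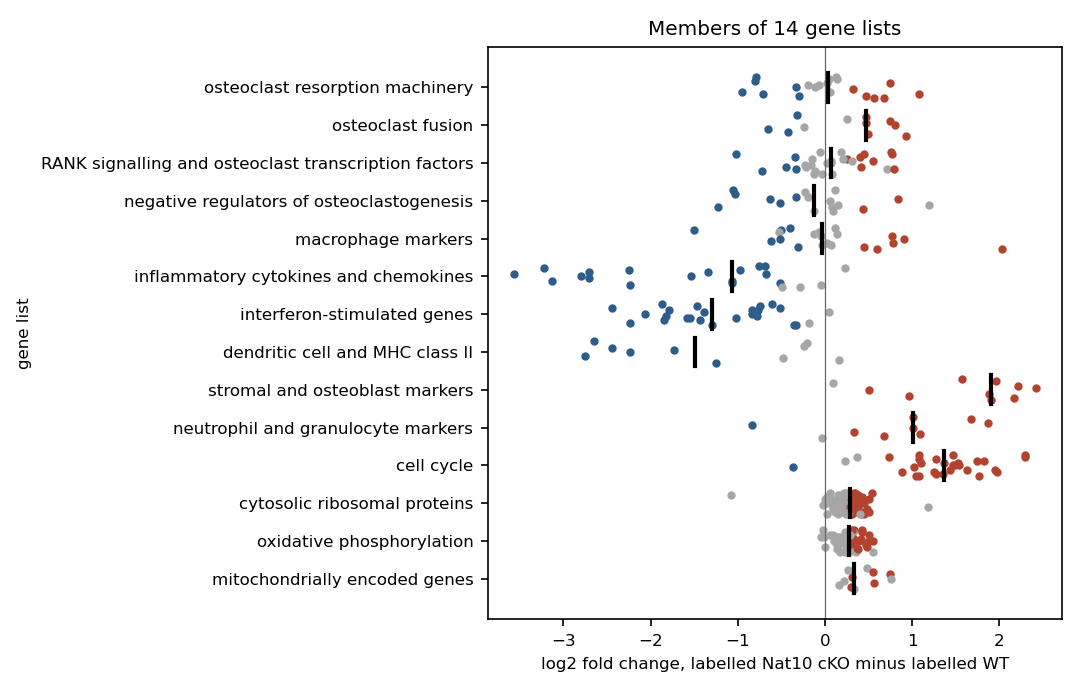
Log2 fold change (libraries labelled Nat10 cKO minus WT) of the measured members of 14 gene lists, with genes called higher in red, called lower in blue, the others in grey and each list's median as a black line. Sp7, which had no count in WT, is not drawn as a point. Medians were -1.07 for inflammatory genes, -1.29 for interferon-stimulated genes, 1.90 for stromal markers, 1.36 for cell cycle genes and 0.03 for resorption machinery.

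Among markers of other cell types that a marrow culture could hold, the stromal and neutrophil lists passed as higher in the libraries labelled Nat10 cKO, and the monocyte and mast cell lists did not pass. Of 11 measured stromal and osteoblast markers, 10 rose and 0 fell, over all genes and adjusted over the list alone (median 1.90, camera adjusted p = 4.49e-19, and adjusted p = 0.0756 with an estimated correlation). Col1a1 stood at 384 ± 0.724 against 82.8 ± 1.29 CPM and Col1a2 at 472 ± 23.6 against 129 ± 7.31 CPM, and Postn and Cxcl12 are among the largest rises above. Runx2, a transcription factor of the osteoblast lineage, had a log2 fold change of 0.09 (adjusted p = 0.790). Sp7, another, had 34 counts in the libraries labelled Nat10 cKO and 0 in WT. Scaled by total counts, that is at least 10.3-fold higher against a floor of 3 counts over the WT group. TMM factors (1.03 and 1.02 in the libraries labelled Nat10 cKO, 0.98 and 0.98 in WT) would lower that bound. The median was 1.90 with Sp7 at the bound of 10.3-fold.

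Of 9 measured neutrophil and granulocyte markers, 7 rose and 1 fell over all genes and adjusted over the list alone (median 1.01, camera adjusted p = 0.00117, and adjusted p = 0.265 with an estimated correlation). Ngp (1.09) and S100a8 (1.01) rose and Mmp8 fell by 0.84. Of 12 monocyte markers, 6 rose and 2 fell over all genes, and 7 rose and 2 fell adjusted over the list alone (median 0.63, camera adjusted p = 0.0630), with fibronectin Fn1 at 1.52 and the proteoglycan Vcan at -1.95. Without WT replicate 2, 3 monocyte markers rose and 2 fell, and without WT replicate 1 the list passed, with a camera adjusted p of 0.0279 in a range up to 0.520 over its alternatives. Of 5 mast cell, basophil and megakaryocyte markers, 2 rose and 0 fell over all genes and adjusted over the list alone (median 0.04, mean 0.49, camera adjusted p = 0.0630). Platelet factor Pf4 stood at 164 ± 23.2 against 58.1 ± 4.41 CPM, and Ppbp at 0.91 lost its call without cKO replicate 1 (0.79), WT replicate 1 (0.76) or WT replicate 2 (1.08) and in DESeq2 (0.91). That list passed without cKO replicate 1, with a camera adjusted p of 0.00957 in a range up to 0.477 over its alternatives. Its median was -0.12 without cKO replicate 2, 0.45 without cKO replicate 1, 0.68 without WT replicate 1 and 0.18 without WT replicate 2. In the B lineage list, 4 members were measured and Ebf1 rose (1.71, 8.55 ± 0.0219 against 2.58 ± 0.333 CPM), over all genes and adjusted over the list alone. Its other members Pax5 (edgeR adjusted p = 0.127), Cd79b (0.403) and Cd79a (0.560) did not pass. They stood at 1.14, 1.52 and 1.15 CPM in the libraries labelled Nat10 cKO. Markers of T and NK cells and of erythroid cells were too low to test, with 0 measured in each list.

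Cell cycle genes were higher in the libraries labelled Nat10 cKO. Of 30 measured, 27 rose and 1 fell, over all genes and adjusted over the list alone (median 1.36, camera adjusted p = 1.36e-18, and adjusted p = 0.0756 with an estimated correlation). Rrm2 was at 24.1 ± 0.680 against 4.85 ± 0.789 CPM, and the topoisomerase Top2a (1.37), the cyclin Ccna2 (1.97) and the replication helicase subunit Mcm6 (1.36) rose. Mki67, the gene of the proliferation antigen Ki-67, was the member that fell (-0.36, adjusted p = 0.0148), and the count of falling members was 0 without cKO replicate 2, WT replicate 1 or WT replicate 2 and with upper-quartile factors. In the wider cell cycle pathway of the deposited annotation, taken up after the results were seen, 39 of 117 tested genes were higher and 6 lower (median 0.15, camera adjusted p = 0.000728, and adjusted p = 0.570 with an estimated correlation). The lower genes of that pathway numbered 11 without cKO replicate 1, 3 without WT replicate 1 and 4 without WT replicate 2, and DESeq2 called 24 higher and 4 lower. The stromal and osteoblast markers were higher in the same libraries. Of 15 measured targets of p53, 4 rose and 2 fell over all genes and adjusted over the list alone (median 0.00456, camera adjusted p = 0.638), with a negative median without WT replicate 2 (-0.025), in DESeq2 (-0.0088) and with RLE factors (-0.0018). The cell cycle inhibitor Cdkn1a fell by 1.05 and Phlda3 rose by 1.37. The wider p53 pathway of that annotation, which also holds cyclins, passed as higher, with 20 of 66 tested genes higher and 10 lower (median 0.24, camera adjusted p = 0.00325, and adjusted p = 0.570 with an estimated correlation), and 6 lower without either WT library.

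Genes of the ribosome and of mitochondrial respiration were higher by smaller amounts. Of 78 cytosolic ribosomal protein genes, 41 rose and 0 fell over all genes, and 52 rose and 0 fell adjusted over the list alone (median 0.29, camera adjusted p = 3.52e-07). With an estimated correlation, the adjusted p = 0.712. Rpl31 rose by 0.54 and Rpl23a by 0.48. Fewer of the ribosomal protein genes passed without either WT library, although the median stayed at 0.28. The median was 0.18 without cKO replicate 2, where fewer also passed, and 0.37 without cKO replicate 1, where more did. Ribosomal protein genes held 4.56% and 5.08% of all counts in the libraries labelled Nat10 cKO against 3.83% and 3.88% in WT. Of 46 nuclear genes of oxidative phosphorylation, 19 rose and 0 fell over all genes, and 26 rose and 0 fell adjusted over the list alone (median 0.28, camera adjusted p = 0.000271), with an adjusted p = 0.722 with an estimated correlation. The cytochrome c oxidase subunit Cox7b rose by 0.55 and Cox8a by 0.50, the latter at 0.32 without cKO replicate 2. The count of rising oxidative phosphorylation genes was 9 in DESeq2, 30 with upper-quartile factors and 29 with library size only. It was lower without either WT library, although the median stayed at 0.26. The count was also lower without cKO replicate 2 (median 0.16) and higher without cKO replicate 1 (median 0.36). Of 11 measured genes encoded in the mitochondrial genome, 5 rose and 0 fell over all genes, and 6 rose and 0 fell adjusted over the list alone (median 0.33, camera adjusted p = 0.00725, and adjusted p = 0.481 with an estimated correlation). The oxidase subunit mt-Co1 rose by 0.74. Fewer genes of the list passed without either WT library or without cKO replicate 2. The median was then 0.23 without WT replicate 1, 0.40 without WT replicate 2 and 0.41 without cKO replicate 2. It was 0.49 without cKO replicate 1. Mitochondrially encoded genes held 2.04% and 2.10% of counts in the libraries labelled Nat10 cKO and 1.33% and 1.55% in WT.

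Lists for ribosome assembly, metabolism and stress did not pass. Of 30 ribosome biogenesis genes, 1 rose and 4 fell over all genes and adjusted over the list alone (median -0.15, camera adjusted p = 0.179), with the nucleolar gene Nop58 at -0.64, and without WT replicate 1 the counts were 0 and 1. The wider pathway of ribosome biogenesis in the deposited annotation, also taken up after the results were seen, passed as lower, with 14 of 71 tested genes lower and 1 higher (median -0.15, camera adjusted p = 0.0364, and adjusted p = 0.60 with an estimated correlation), and 9 lower without WT replicate 1. Of 16 glycolysis genes, 5 rose and 0 fell over all genes, and 6 rose and 0 fell adjusted over the list alone (median 0.15, camera adjusted p = 0.0630). That list passed with library size only (camera adjusted p = 0.0374) and without cKO replicate 1 (camera adjusted p = 0.0188), in a range up to 0.722 over its alternatives, while 0 of its genes rose without WT replicate 1 and 2 without WT replicate 2. Of 19 cholesterol synthesis genes, 4 rose and 0 fell over all genes and adjusted over the list alone (median 0.24, camera adjusted p = 0.0877), with the sterol sensor Insig1 at 0.58 and the synthesis enzyme Nsdhl at 1.05. Without cKO replicate 2 the median of these genes was 0.08, with 3 rising and 1 falling, and DESeq2 called 2 as rising and 0 as falling. Of 19 genes of the unfolded protein and integrated stress response, 4 rose and 4 fell over all genes, and 5 rose and 5 fell adjusted over the list alone (median -0.02, camera adjusted p = 0.673). The phosphatase subunit Ppp1r15a fell by 1.13 and the cystine transporter Slc7a11 fell by 0.92, and the chaperone Pdia4 rose by 0.56. The median of the stress list was positive without cKO replicate 2 (0.037), with upper-quartile factors (0.07), with library size only (0.04) and after the length and GC correction (0.05). It was -0.096 without cKO replicate 1 and -0.048 without WT replicate 1. The list of immediate early and heat shock genes can mark handling at harvest, but it shares Fos and Jun with the RANK signalling list. Of its 14 measured genes, 2 rose and 5 fell over all genes. Adjusted over the list alone, 3 rose and 5 fell (median -0.11, mean 0.00124, camera adjusted p = 0.529), with Egr1 at -0.76 and Hspa1b at 1.40. Of these genes, 3 fell without WT replicate 2, and the median was -0.014 without cKO replicate 2 and -0.06 without WT replicate 1.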

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

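The length and GC correction and the fit without the 10 largest genes were chosen after seeing the data. Of 3302 called genes, 3237 kept their call and direction with RLE factors, 2762 with upper-quartile factors, 2904 with library size only, 3211 in limma-voom, 2088 in DESeq2, 3134 of 3295 testable ones after the length and GC correction, 1967 of 3297 without WT replicate 1 and 1752 of 3298 without WT replicate 2. DESeq2 called 2114 genes, 932 of them higher. A minimum of 1 on the absolute log2 scale left 929 genes, 662 higher and 267 lower, by its own construction. With each library left out in turn, the edgeR test called 1837 to 3501 genes, 864 to 1576 higher and 973 to 1925 lower. The cause was not tested. Of 115 called genes among the 125 named, 22 lost the call without WT replicate 1, 20 without WT replicate 2, and 4 without each library labelled Nat10 cKO.

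Nat10 was not called under any alternative. Nfatc1 was called under all but the minimum on the log2 scale (0.55) and the fit without WT replicate 2, and its log2 fold change ranged from 0.45 to 0.63 over the left-out libraries. Over the 125 named genes and their alternatives, 1735 of 1874 results kept direction and side of the threshold, 125 lost the call, 6 gained one and 8 changed sign. The sign changes were of 2 uncalled genes. Itga2b was at -0.029 after the length and GC correction, with -0.12 to 0.18 over the left-out libraries. Kit was at -0.032 in DESeq2, -0.035 in limma-voom and -0.0050 with the replicate block, with -0.72 to 0.45 over the left-out libraries. The cause was not tested.

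With an estimated correlation, 0 lists passed. Adjusted p was then 0.0756 for the inflammatory, interferon, dendritic cell, stromal and cell cycle lists, 0.265 for neutrophil markers, 0.481 for mitochondrially encoded genes, 0.712 for ribosomal proteins and 0.722 for oxidative phosphorylation. The correlation itself was estimated at -0.030 for interferon, -0.063 for dendritic cell, -0.017 for stromal, 0.0043 for cell cycle and -0.079 for neutrophil genes. These lie below the preset 0.01, so a higher correlation does not account for the larger p of those lists. It was 0.20 for inflammatory genes, 0.26 for mitochondrially encoded genes, 0.73 for ribosomal proteins and 0.67 for oxidative phosphorylation. In fry, which does not compare a list with other genes, adjusted p was 0.16 for ribosomal proteins, 0.238 for oxidative phosphorylation and 0.101 for mitochondrially encoded genes. The inflammatory, dendritic cell, stromal and cell cycle lists passed in fry (adjusted p = 0.00565 each). Interferon-stimulated genes (0.00195) and neutrophil markers (0.00144) passed as well. So did negative regulators (0.0330), ribosome biogenesis (0.0483) and immediate early genes (0.0365). Glycolysis passed with library size only (0.0374). The median shift of log2 fold changes over all tested genes was 0.098 with upper-quartile factors and 0.066 with library size only, and list medians were then -0.034 and -0.064 for negative regulators, -0.050 and -0.082 for ribosome biogenesis and 0.25 and 0.22 for glycolysis. Over the left-out libraries, camera adjusted p ranged from 0.651 to 0.869 for resorption machinery, 0.309 to 0.869 for V-ATPase subunits and 0.431 to 0.981 for lysosome genes, all uncalled but with changes of direction, and from 0.0199 to 0.131 for negative regulators, 0.0279 to 0.243 for monocyte markers, 0.00957 to 0.124 for mast cell markers and 0.0188 to 0.196 for glycolysis. The cause was not tested.

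The labels share replicate numbers across groups but do not say that a number marks a shared animal or day, and deviations of same-numbered libraries correlated at 0.112 over 2 pairs. With the replicate block, 4301 genes were called, 2126 higher and 2175 lower, and negative regulators (0.0235), mast cell markers (0.0357) and glycolysis (0.0245) passed. Low genes were the less well measured at this depth and number of libraries, since simulated 1.5-fold changes were recovered for 2 of 19 genes (10.5%) under 10 CPM and 34 of 46 (73.9%) at or over it, and 2-fold changes for 10 of 25 and 41 of 41. Depth, the number of libraries and the number of changed genes were not varied. The 200 simulated changes are fewer than the 3302 genes called in the data. That makes the adjustment stricter, so these shares need not hold for the data.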

Other observations

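Pathways from the annotation in the deposited table, the members named here, the 3 tests on Nat10, the test on macrophage share and the liver markers were chosen after the results were seen. Of 45 proteasome genes tested, 23 were lower and 0 higher in the libraries labelled Nat10 cKO (median -0.32, camera adjusted p = 1.19e-05, and adjusted p = 0.634 with an estimated correlation). The immunoproteasome subunits Psmb10 (74.2 against 149 CPM), Psmb8 (-0.65) and Psmb9 (-0.62) and the activator subunits Psme2 (-0.71) and Psme1 (-0.50), which are induced by interferon gamma, fell, and so did subunits of the constitutive proteasome such as Psmb5 (-0.54), Psmd11 (-0.60) and Psmc5 (-0.48). Fewer proteasome genes passed without either WT library, although the median was -0.31 without WT replicate 2 and -0.35 without WT replicate 1. Of 27 genes of the citrate cycle, 14 were higher and 1 lower (median 0.29, camera adjusted p = 0.00325, and adjusted p = 0.727 with an estimated correlation). The isocitrate dehydrogenase genes Idh1 (0.50), Idh2 (0.66) and Idh3a (0.64) rose, and Pcx, which encodes pyruvate carboxylase, fell by 0.53. Fewer citrate cycle genes passed as higher without either WT library, with medians of 0.25 without WT replicate 1 and 0.31 without WT replicate 2. Pcx was not called without WT replicate 2.

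Over 311 such pathways, 23 passed as higher and 51 as lower with camera, and 0 with an estimated correlation, where the smallest adjusted p = 0.570. In the NF-kappa B pathway 41 of 86 genes fell and 6 rose (camera adjusted p = 2.42e-15), and in the TNF pathway 37 of 95 fell and 5 rose (camera adjusted p = 4.98e-15). Without WT replicate 2, 3 genes rose in the first and 1 in the second. In ECM-receptor interaction, 24 of 50 rose and 10 fell (camera adjusted p = 1.10e-06), with 6 lower without WT replicate 2. The pathway named osteoclast differentiation, which holds many cytokine and NF-kappa B genes, did not pass, with 17 of 99 genes higher and 27 lower (camera adjusted p = 0.0653).

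Transcripts of liver proteins were seen mainly in the WT libraries. Over 20 liver genes the summed counts were 755 and 470 in WT replicates 1 and 2 and 12 and 19 in cKO replicates 1 and 2, and 18 of the 20 were higher in both WT libraries. Alb had 428 and 251 counts in WT against 3 and 14, and Ahsg had 51 and 25 against 0 and 0. The source of these transcripts is not known and was not tested.

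Counts of Nat10 were similar in both groups. An exchange of the group labels with loss of the transcript would put Nat10 at least 1 higher in the libraries labelled Nat10 cKO, and the upper bound of its 95% interval, 0.080, argues against that. Too few counts would leave a loss of 1 inside the interval, and the lower bound, -0.56, argues against that as well. A deletion of part of the gene that leaves a counted transcript may remain, since the fold change of the whole gene, -0.24, has no counts per exon beside it. These cannot be told apart further without such counts, and a knockout that had not taken place in the cells sequenced was not tested.

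Stromal and matrix genes were higher in the libraries labelled Nat10 cKO. In a second list of 30 other stromal markers, written before their values were seen, of which 17 were at 1 CPM or more in both WT libraries, 19 of 23 measured (82.6%) were higher and 0 lower, with a median of 1.46, which is consistent with more stromal cells in those cultures as a hypothesis. Bgn stood at 130 against 47.1 CPM and Acta2 at 167 against 60.2 CPM, among the most abundant of them, but Lox, the most abundant, was at 933 against 892 CPM. Length or GC bias is argued against by a median of 1.83 for the first list after that correction, while the genotype and any unrecorded batch, which the labels do not separate, stay open and untested. A larger share of a single stromal population stays open as well. A rule set before the values were seen took Cochran's Q p under 0.05, unequal rises, as evidence against it. The log2 fold changes of the n = 15 most abundant markers did differ by more than their errors (Cochran's Q, chi-square approximation, p = 2.27e-50). Lox was at 0.07 and Mmp2 at 0.08. That rule made no allowance for markers that other cells also express, which would rise less. Unequal rises therefore do not exclude this explanation, and the test cannot decide the question.

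Inflammatory and interferon genes were lower in the libraries labelled Nat10 cKO. A lower share of all macrophages, as the only change, would lower their markers by about the median of the inflammatory list, -1.07. The macrophage median was instead -0.031 (bootstrap SE 0.124), and 1 of 21 markers lay at or below -1.07. These markers went both ways, with 6 called higher and 6 lower, so their median is a weak measure of cell share. Loss of only an activated part of the macrophages was not tested. Length or GC bias is argued against by an inflammatory median of -1.09 after the correction. The genotype, another activation state of the WT cultures and an unrecorded batch may each remain as explanations, and these data do not separate them. The liver transcripts were lower in the same libraries, with 12 and 19 counts against 755 and 470, and whether they share a source with this change was not tested.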
